A study of Mus musculus with 4 samples.

How the data were processed

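Total RNA from pools of 50 mouse oocytes was amplified from 240 pg in 2 rounds and labelled with CyDyes, per the labels' protocols. Each of 4 arrays compared 1 pressure-treated pool (Cy5, red) with 1 control pool (Cy3, green), per the labels. The deposited scanner files hold the mean intensity and the median local background intensity of each spot in both channels, produced with Agilent Feature Extraction 9.5.1.1, per the submitters' processing notes. They also hold processed signals, which that software had background-subtracted and dye-normalized, per the file headers, and their log10 ratio of red over green. The authors' value table equals this log10 ratio to within 5.0e-10 on every array, with a median of 0 in each column, so its scale and direction were settled from the scanner files. It was used as an alternative. Probe positions are those of the files, in mouse build mm7.

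From the deposited intensity values, background was corrected by normexp with an offset of 50 and each array was normalized by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Control spots and spots with outlier flags were then left out, and no spot was saturated. Spots of a probe were averaged. A probe was kept if well above background on at least 3 of 4 arrays in the same channel, which left 8108 of 41174 probes. Each gene was represented by its brightest kept probe, giving 6941 genes, of which 6889 had a value on every array. Gene names came from the files. They were updated through a RefSeq table of assembly GRCm38.p6, used for names only. Of the tested genes 5034 were matched by accession, 810 by symbol and 357 by synonym, 162 kept the name in the file and 578 had no symbol.

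The log2 ratio was tested against 0 with lmFit and eBayes, with Benjamini-Hochberg adjustment over all genes and, for gene lists, also over the list alone. Gene lists were tested with camera at a preset correlation of 0.01, and with an estimated correlation and with fry as alternatives. fry tests whether a list's genes move on balance one way and does not compare them with other genes. Of 18 lists fixed before the data were examined, the 16 with at least 5 measured genes were tested. Genes were named by a rule also fixed then: the called genes with the greatest change, or, as none was called, the 10 per direction with the smallest p among those of the same sign on all 4 arrays, the 2 members of each list with the smallest p, and a short list of stress and oocyte genes. Names that are clone or accession identifiers were left out, and some genes that the rule names are not reported here.

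A channel not well above background on any array has only a bound. It was taken from the brighter channel's mean against the higher of the dimmest detected signal and the probe's own, per channel after loess and Aquantile. The bound does not cover the spread between arrays. The tests were tried on simulated log2 ratios of 6941 genes with 200 changed, in 20 runs, with 5.6 false calls a run. In further simulated values a shift of the size of the ribosomal list's was added to all its genes on every array, and camera recovered it in every run. Genes were drawn independently and the preset correlation was used, so this recovery says little about the real call. Camera with an estimated correlation was not tried on simulated values.

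Alternatives fixed before the data were examined covered the background correction, the normalization within and between arrays, the filter on dim probes, the mean over a gene's probes, the eBayes settings, array weights, a separate-channel model, the authors' values and leaving out each array. All 4 arrays lie on 1 slide with 1 scan, so no batch block could be fitted. Alternatives with the sign of replicate 1 turned, and with adjustment for the base composition of the 60 nt probes, were chosen after seeing the data.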

Results

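Gene expression was measured in mouse oocytes kept for 60 min under a hydrostatic pressure of 20 MPa at 37 °C and in control oocytes held under the same conditions without the pressure. Each of 4 arrays carried 1 treated and 1 control pool of 50 oocytes, and the submitters describe the 4 replicates as biological. By the labels the treated pool was in the red (Cy5) channel and the control pool in the green (Cy3) channel on all 4 arrays, so dye and treatment were not separated. Of 43379 spots other than controls, between 7049 and 11155 were well above background in the treated channel and between 8309 and 10837 in the control channel. After the filter on dim probes, 6941 genes were tested. Each log2 ratio below is treated over control, and the number of arrays limits its precision.

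The comparison asks which transcripts differ in oocytes after the pressure treatment. The ribosomal proteins, the protein components of the cytosolic ribosome, were the list with the clearest shift toward lower values in treated oocytes. The median log2 ratio over the 63 measured ribosomal protein genes was -0.37, and 53 of the 63 had a mean below 0. The list's median on the single arrays was -0.49, -0.14, -0.40 and -0.38 for replicates 1 to 4, a mean of -0.35 ± 0.15 (SD, n = 4). Genes of oxidative phosphorylation, the mitochondrial respiratory chain and ATP synthase, had a median of -0.16, with 45 of 61 below 0. No single gene of the 6941 passed the test in either direction.

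With limma's camera at its preset correlation of 0.01, 3 of 16 lists passed, all toward lower values. The adjusted p was 4.2e-10 for ribosomal proteins, 0.0013 for oxidative phosphorylation and 0.039 for the meiotic cell cycle. At the preset, camera's degrees of freedom come from the number of genes, so these p-values do not measure the spread between the 4 arrays. None of the 3 calls held with a correlation estimated from the data. Camera then gave an adjusted p of 0.056 for ribosomal proteins, 0.14 for oxidative phosphorylation and 0.78 for the meiotic cell cycle. The estimated correlations were -0.0070, -0.0088 and 0.033 in that order. For the first 2 lists the estimate lay below the preset, so a higher correlation between genes does not account for the loss of their calls. With an estimated correlation camera also has fewer degrees of freedom, 3 from the arrays in place of a number set by the genes. An exact sign-flip test of a list's median over 4 arrays cannot go below a two-sided p of 0.125, and the ribosomal and oxidative phosphorylation medians lay below 0 on 4 of 4 arrays. With the sign of replicate 1 turned, an alternative chosen after seeing the data, 0 lists passed.

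**Figure D1:**
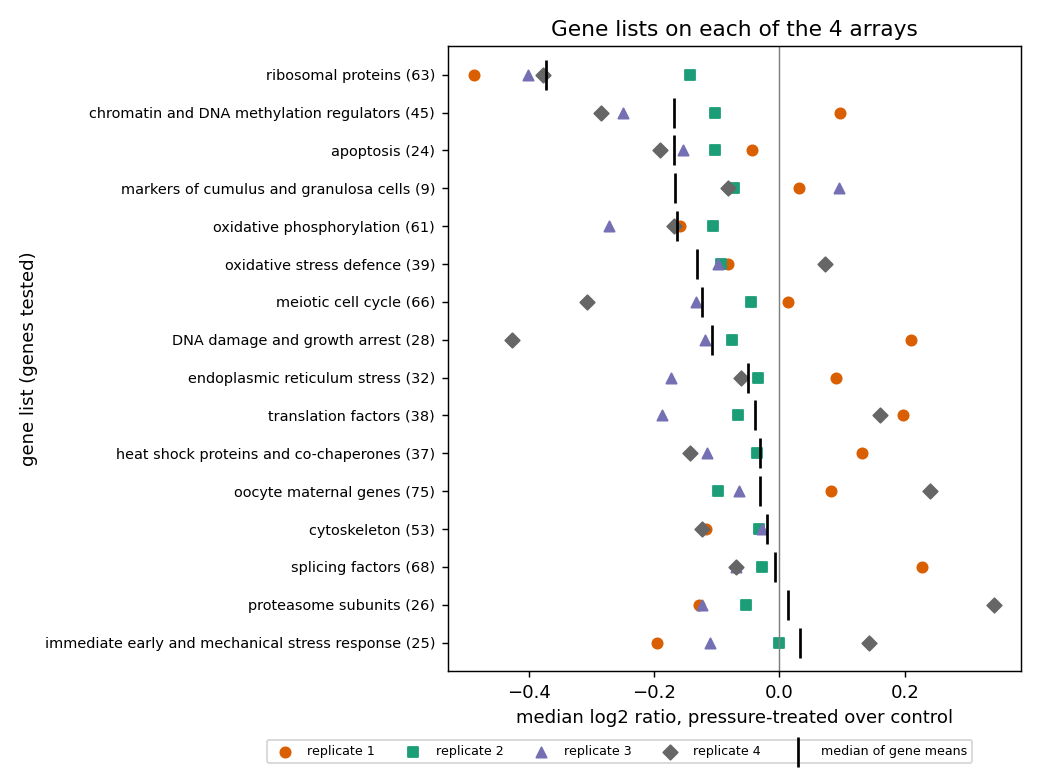
Median log2 ratio (treated over control, horizontal axis) of the 16 tested gene lists (vertical axis, genes tested in brackets) on each of the 4 arrays, with symbols for replicates 1 to 4 and a black bar for the median of the gene means. The ribosomal protein medians lie between -0.49 and -0.14, all below 0.

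Among ribosomal protein genes, 0 members passed over all genes tested and 0 adjusted over the list alone, where the lowest adjusted p from limma was 0.12. Rps29, a small-subunit protein, had a log2 ratio of -0.95 ± 0.18 (SE, n = 4), with its probe at 67099313 to 67100211 on chromosome 12 of mm7. Of the 61 members with a value on every array, 22 were below 0 on 4 of 4 arrays, Rps29 among them. Of all genes with 4 values, 9.32% lay below 0 on every array, where chance gives 6.25%. With median centring, which moved the median of all tested genes to -0.34, Rps29 was at -1.64. With replicate 1 turned it was at -0.36.

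**Figure D2:**
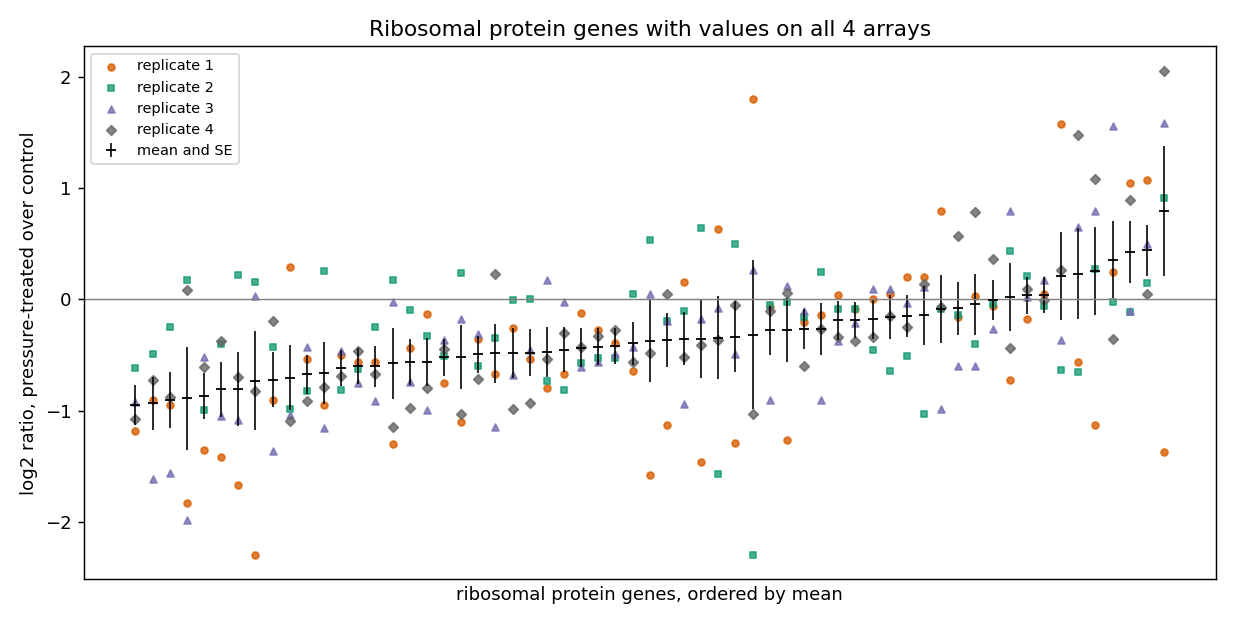
Log2 ratio (treated over control, vertical axis) of the 61 ribosomal protein genes with a value on all 4 arrays (horizontal axis, ordered by mean), with symbols for replicates 1 to 4 and black bars for the mean and its SE. Rps29 has a mean of -0.95, and 22 of the genes lie below 0 on every array.

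Of the 61 oxidative phosphorylation genes, 0 passed singly, also adjusted over the list alone. Ndufc1 and Ndufb11, subunits of respiratory complex I, had log2 ratios of -1.19 ± 0.29 and -1.15 ± 0.31 (SE, n = 4), and 16 genes of the list were below 0 on all 4 arrays. The meiotic cell cycle list had a median of -0.12 over 66 genes, with 45 below 0 and 0 passing singly or adjusted over the list alone. Cdc16, a subunit of the anaphase-promoting complex, had -0.80 ± 0.21, and Cks2, a cyclin-dependent kinase subunit needed for meiosis, had -1.06 ± 0.29 (SE, n = 4). Over the settings Cdc16 ran from -1.44 to -0.12 and Cks2 from -1.65 to -0.33. The meiotic call was also lost without replicate 2, 3 or 4, where camera's adjusted p was 0.065, 0.072 and 0.46. The meiotic median was -0.23 to -0.089 when 1 array was left out. The call was lost as well with processed signals (0.16), no background subtraction (0.066), array weights (0.11), the authors' values (0.16), base composition adjusted (0.13) and fry (0.37).

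In the gene-wise test by limma, 0 genes were higher and 0 lower at an adjusted p of 0.05. The mean differed at least 2-fold for 144 genes, 0 of which passed, and 1 higher and 50 lower among them were under an unadjusted p of 0.05. The lowest adjusted p was 0.93. Without adjustment 290 genes were under 0.05 (51 higher, 239 lower), against 347 by chance. Over all tested genes, 3302 means lay above 0 and 3639 below, a lean that depended on the filter. It was 2075 above and 1838 below with both channels detected on all 4 arrays, and 14207 and 13690 with no filter on dim probes. With replicate 1 turned, chosen after seeing the data, the lean among genes under 0.05 reversed, with 936 such genes (563 higher, 373 lower). The lowest adjusted p from limma was then 0.054. Over all tested genes the means then leaned further toward lower, with 2971 above 0 and 3970 below. Of 6889 genes with 4 values, 642 were below 0 on every array (9.32%) and 202 above (2.93%), where chance gives 6.25% each way. Both directions together came to 12.25%, against 12.5% by chance. In simulated data with the spread of these arrays, 70.0% of log2 changes of 2 and 9.18% of changes of 1 were recovered among 6941 genes.

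The genes with the smallest p among those below 0 on all 4 arrays are given as values that did not pass. Emb (embigin, a membrane glycoprotein; probe at 114482837 to 114482896 on chromosome 13) had a log2 ratio of -1.59 ± 0.22 (SE, n = 4), and like Osbpl5 and Serpinc1 it was well above background on 2 arrays in the treated channel and 4 in the control channel. Pole3, a subunit of DNA polymerase epsilon (probe at 61956359 to 61956418 on chromosome 4), had -1.76 ± 0.30. Ssu72, a phosphatase of the RNA polymerase II tail, had -1.29 ± 0.22. Osbpl5, a lipid transfer protein, had -1.62 ± 0.33. The log2 ratios of Aagab, Mphosph6, Dazap2, Serpinc1 and Aadat were -1.18, -1.13, -0.96, -0.91 and -0.90, and Rps29 completes the 10. The size of several values depends on the processing. With processed signals Emb was at -3.43, Ssu72 at -2.99, Osbpl5 at -3.96, Aagab at -2.63 and Serpinc1 at -2.70. With median centring Dazap2 was at -1.70 and Mphosph6 at -1.70. Turning replicate 1 brings any gene of 1 sign on all arrays nearer 0. Emb was then at -0.68, Ssu72 at -0.77, Osbpl5 at -0.43, Aagab at -0.74 and Serpinc1 at -0.39.

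Above 0 on all 4 arrays, and likewise not passing, Cdk14, a cyclin-dependent kinase (probe at 4809831 to 4809890 on chromosome 5), had a log2 ratio of 0.68 ± 0.16 (SE, n = 4). Cldnd1, a claudin-domain membrane protein, had 1.12 ± 0.29. Car9, a carbonic anhydrase, had 0.65 ± 0.17, and Cnot6l, a deadenylase that shortens poly(A) tails, had 0.73 ± 0.21. The log2 ratios of Slc22a23, Dpy19l1, Wars2, Sidt2, Fam204a and Pbx3 were 0.80, 0.73, 0.71, 0.59, 0.56 and 0.56. The other kept probe of Cnot6l and of Sidt2 had the opposite sign, and the means over their probes were 0.091 and 0.28. The ratios of Cnot6l and Fam204a were below 0 with median centring, which moved the median of all tested genes to -0.34. It also brought Cdk14 to 0.22, Cldnd1 to 0.64, Car9 to 0.37, Slc22a23 to 0.11, Dpy19l1 to 0.12, Sidt2 to 0.096 and Pbx3 to 0.094. Processed signals put Cdk14 at 1.47, Car9 at 1.39, Sidt2 at 1.40, Pbx3 at 0.85, Cnot6l at 0.30 and Wars2 at 3.20, and Wars2 was well above background on 4 arrays in the treated channel and 2 in the control channel.

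The stress lists did not pass, and the members named here and in the next paragraphs are those with the smallest p or given by the rule, none of which passed. Heat shock proteins and co-chaperones had a median log2 ratio of -0.03 over 37 genes (camera's adjusted p = 0.94), with Dnajc8 at -1.10 ± 0.33 and Hsp90aa1 at -0.77 ± 0.36 (SE, n = 4). Hspa1a, Hsph1 and Hspa8 were not among the tested genes, and neither was Actb. The oxidative stress list had a median of -0.13 over 39 genes (camera's adjusted p = 0.82), and Sod1 and Sod2, the cytosolic and mitochondrial superoxide dismutases, had -0.44 ± 0.24 and -0.41 ± 0.25 (SE, n = 4). Gsto1 and Glrx5 of this list had -0.77 and -0.84. Endoplasmic reticulum stress had -0.05 over 32 genes, with Erp29 at 0.50 and Manf at -0.40. The list of DNA damage and growth arrest had -0.11 over 28, with Trp53inp1 at -0.91, Ung at 0.37 and Gadd45a at 0.12 ± 0.21. Apoptosis had a median of -0.17 over 24 genes, with Cycs at -0.44 and Xiap not well above background in any treated channel. Immediate early and mechanical stress genes had 0.03 over 25, with Maff at 0.78. Maff was well above background on 3 arrays in the treated channel and 1 in the control channel, and ran from 0.38 to 3.16 over the settings. Fos was not well above background in the treated channel on any array, and in the control channel it was on 3. The bound from the means over arrays was 1.50-fold higher in control pools, which leaves out the spread between arrays. Single arrays ran from -1.09 to -5.0e-04, so the bound is not a lower limit for each array. It is also open to dye bias, and Fos did not pass (limma's adjusted p = 0.93). Leaving out replicate 3 moved Hsp90aa1 to -0.36, Sod1 to -0.24 and Sod2 to -0.17, and leaving out replicate 2 moved Glrx5 to -0.52 and Trp53inp1 to -0.53. Leaving out 1 array gave 0.41 to 1.26 for Maff and -0.038 to 0.28 for Gadd45a.

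Oocyte maternal genes had a median log2 ratio of -0.03 over 75 genes, with a mean of 0.01, and did not pass (camera's adjusted p = 0.89). Gdf9 and Bmp15, growth factors secreted by the oocyte, had 0.48 ± 0.28 and 0.39 ± 0.44 (SE, n = 4), and the zona pellucida gene Zp3 had -0.03 ± 0.23. Fbxw24 and Tcl1 had 0.60 and -0.59. Leaving out 1 array gave 0.24 to 0.76 for Gdf9, -0.056 to 0.84 for Bmp15 and -0.22 to 0.12 for Zp3, and the 2 probes of Zp3 differed in sign. Chromatin and DNA methylation regulators had a median of -0.17 over 45 genes (camera's adjusted p = 0.091), with the histone genes H3f3b at -1.32 on 3 arrays and H2az1 at -0.72. This list passed without replicate 1 (0.031) and with median centring (0.018), and its adjusted p was 0.82 with an estimated correlation. The other kept probe of H3f3b had the opposite sign, and the mean over its probes was -0.34. The medians were -0.04 for translation factors (38 genes), 0.01 for proteasome subunits (26), -0.01 for splicing factors (68) and -0.02 for the cytoskeleton (53). None of these 4 passed with camera. Members with the smallest p were Eif4ebp1 (-0.72) and Eif4g2 (-0.74), Psmb4 (-0.78) and Psme4 (-0.84), Bcas2 (-1.05), and Tuba1a (-0.64) and Limk1 (0.93). Without replicate 4, Eif4g2 was at -0.49 and Psme4 at -0.49, and without replicate 1 Bcas2 was at -0.64. The sign of the median differed from that of the test for heat shock, maternal, proteasome and splicing lists. The cytoskeleton list passed limma's fry, with an adjusted p of 0.027, as did ribosomal proteins (0.0078) and oxidative phosphorylation (0.031).

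Markers of other cell types gave few measured genes. Cumulus and granulosa markers had a median log2 ratio of -0.17 over 9 genes and did not pass (camera's adjusted p = 0.82). Markers of blood and immune cells (4 genes) and of oviduct epithelium, endothelium and stroma (4 genes) were under the minimum of 5 genes for the test, with medians of 0.21 and 0.04. Nr5a2 of the first list had -0.22, Srgn and Hba-a1 of the second -0.52 and 0.28, and Acta2 and Kdr of the third 0.83 and -0.23. Hsd17b1, also of the first list, was not well above background in any treated channel. Leaving out 1 array gave -0.33 to -0.079 for Nr5a2, 0.096 to 0.54 for Hba-a1, 0.51 to 1.34 for Acta2 and -0.48 to 0.14 for Kdr.

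Replicate 1 stood apart from the other 3 arrays. Across all probes its log2 ratios correlated with those of replicates 2, 3 and 4 at r = -0.17, -0.15 and -0.19, whereas the other pairs had r of 0.29, 0.09 and 0.23. These correlations are across probes, which are not independent replicates. The 99th percentile of net signal in the treated channel was 2.56 times that of the control channel on replicate 1 and 0.25 to 0.39 times on the others. Without replicate 1, 0 genes passed and 760 were under an unadjusted p of 0.05, against 290 with it.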

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

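Both tests of exchanged dyes on replicate 1 were chosen after the result was seen, the second when the value of the first was already known. Of 85 sets of 4 array values, 8 had 1 array far from the other 3, where chance gives about 5%. The ratio of treated to control net signal at the 99th percentile was 2.56 on replicate 1, against 0.25 to 0.39 on the others. Pole3 had a log2 ratio of -2.82 on replicate 4, with the others between -1.46 and -1.35. Ssu72 had -1.95 on replicate 3, against -1.09 to -1.03. Tcl1, an oocyte gene, had 0.21 on replicate 2, against -0.91 to -0.80. Hsd17b1, a granulosa cell gene that was not well above background in any treated channel, had -2.26 on replicate 1, against -0.19 to -0.07. The median of the oxidative stress list was 0.072 on replicate 4 and between -0.10 and -0.08 elsewhere. The proteasome median was 0.34 on replicate 4, against -0.13 to -0.05. The median of the splicing factors was 0.23 on replicate 1, against -0.07 to -0.03.

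Replicate 1 ran against the other 3 arrays. Noise of dim spots is argued against, because among the brightest 25% of the genes its correlation with the mean of the others was -0.52. Base composition of the probes is argued against as the whole cause, because the correlation over all tested genes was -0.29 before and -0.23 after adjustment for it. Exchanged dyes on this array stay open, because the 2 tests point opposite ways: the ribosomal list lay at -0.49 on replicate 1, the same direction as on the other arrays (SE of its members' mean 0.10), whereas with the sign turned the lowest of its correlations with another array was 0.29 among bright genes, above the lowest pair among the others (0.14). A dye effect on ribosomal probes would keep their sign on an exchanged array. The turned correlation follows from the negative one already seen, so neither test decides. Exchanged dyes would also reverse the ratio of treated to control net signal, which was 2.56 on replicate 1 and 0.25 to 0.39 on the others. The log2 ratio correlated with the probes' GC percentage at r = -0.20 on replicate 1 and at 0.13, 0.24 and 0.23 on replicates 2 to 4. Neither of these was set as a test, and no biological explanation was tested.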

How the results depend on the processing

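The alternatives with replicate 1 turned and with base composition adjusted were chosen after seeing the data. Under every alternative run, 0 genes passed in either direction, with unadjusted counts from 134 to 936. The lowest adjusted p from limma was 0.054 with replicate 1 turned and 0.17 without replicate 1, against 0.93 in the reported setting. The reported test is itself the paired analysis, because each ratio sets the 2 pools of an array against each other. The slide and scan block was not run, since there was 1 slide and 1 scan. Against 3 lists in the reported setting, 0 passed with an estimated correlation in camera and 0 with replicate 1 turned. Of the 3, only the meiotic list had an estimated correlation above the preset. A higher correlation thus does not account for the loss of the other calls. What else differs between the 2 forms of camera is the degrees of freedom, 3 from the arrays against a number set by the genes. Leaving out 1 array gave 2 to 4 lists. The ribosomal median ranged from -0.89 to -0.18, the oxidative phosphorylation median from -0.60 to -0.07 and the meiotic median from -0.67 to -0.066 over the settings. Processed signals and the authors' values moved the median of all tested genes to -0.12. Median centring moved it to -0.34 and turned the log2 ratios of Cnot6l (-0.063), Fam204a (-0.017), Erp29 (-0.019), Ung (-0.29), Gdf9 (-0.37), Bmp15 (-0.38) and Gadd45a (-0.29). Gdf9 was at -0.044 with processed signals and with the authors' values, and Bmp15 at -0.11 with array weights. Xiap was at 0.17 with no filter on dim probes, H3f3b at 0.12 with both channels detected on all arrays, and Zp3 at 0.012 with the mean over its probes. With replicate 1 turned, Bcas2 was at 0.094, Hsd17b1 at 0.48, Nr5a2 at 0.10 and Zp3 at 0.20. Leaving out 1 array turned Kdr (range -0.48 to 0.14), Bmp15 (-0.056 to 0.84), Gadd45a (-0.038 to 0.28) and Zp3 (-0.22 to 0.12); for these reversals the cause was not tested. Apart from leaving out arrays, alternatives moved 498 values of named genes, of which 481 kept their direction, and left 339 equal, since Aquantile, the eBayes settings and the separate-channel model cannot move a mean ratio and the filters and the mean over probes moved few. Signal over background limits what was measured: 1658 of the tested genes were detected on at least 3 arrays in 1 channel only.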

Other observations

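The test of a lower yield was chosen after the result was seen; the others in this part were set before theirs, except that the margin of 2 SE (1 SD for 4 arrays) on the last bound for mitochondrial genes was set afterwards. Mitochondrial ribosomal protein genes (Mrpl and Mrps), which translate inside the mitochondrion, were examined beside the cytosolic ones. Their median log2 ratio, averaged over the 4 arrays, was -0.12 ± 0.04 (SD, n = 4), and 32 of 43 genes lay below 0. Over genes, the measure given first for the other lists, their median was -0.18. By that measure cytosolic ribosomal proteins had -0.37 and oxidative phosphorylation -0.16. Short nuclear-encoded transcripts in general may be lower, since the mitochondrial list exceeded the cytosolic by 0.23 ± 0.07 (SE, n = 4) but exceeded 0.5 of the cytosolic median by 0.06 ± 0.07 (SD, n = 4). The bound as first written, with no margin on this value, was met, but by less than its SD between arrays, so the explanation stays open.

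The ribosomal protein list lay toward lower values in the treated channel at camera's preset correlation, a call lost with an estimated correlation (adjusted p = 0.056) and with replicate 1 turned (0.30), and 0 of its genes passed singly. Brightness-dependent bias is argued against, because the list's median of -0.37 lay at percentile 0 of 10000 random lists matched on intensity (95% of them from -0.17 to 0.04). Such a low position was not particular to this list. Oxidative phosphorylation (percentile 0.64), apoptosis (1.13), chromatin regulators (1.37) and the meiotic cell cycle (2.23) also lay below the central 95% of their matched lists. Base composition of the probes is argued against as the whole cause, because the median over arrays was -0.33 ± 0.09 (SE, n = 4) after adjustment. A lower RNA or cDNA yield of the treated pool predicts a median of 0 or more on replicate 1, where red was brighter. The value of -0.49 goes against it only if red is the treated pool there, and exchanged dyes stay open on that array. In either case 1 array cannot exclude a lower yield. A gene-specific difference between the dyes cannot be told apart from the pressure, since 0 arrays carried the treated pool in green by the labels, and an effect of the pressure stays equally open.

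For 4 arrays there are 8 ways to exchange the pools within arrays, too few for a share under 0.05. The real arrangement gave 3 lists and the highest other gave 2. For single genes the real arrangement gave 0, the highest other gave 0, and all 8 arrangements thus gave as many. Exchanging replicate 1 gave 936 genes under an unadjusted p of 0.05, against 290, which restates its negative correlation with the other arrays.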
